A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

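Relative tag abundance was measured on 2 two-colour tag microarrays (experiment 1 and experiment 2, called array 1 and array 2) for pools of haploid Saccharomyces cerevisiae deletion strains. Per the labels' protocols, a pool of 5896 heterozygous diploid knockout strains that can be converted to haploids was transformed with a control plasmid or with a GAL1-LCD1 plasmid, both selected by URA3. The pools were sporulated, and haploids were selected for 3 days at 30 °C on medium whose only carbon source was galactose at 2%. The strain tags were amplified from genomic DNA with primers common to all upstream or all downstream tags, although the molecule field of the labels reads total RNA. Tags of the control pool were labelled with Cy5 and tags of the LCD1 pool with Cy3 on both arrays. Both dye products were hybridised together to a Hopkins tag array, which was read with a GenePix scanner and the GenePix 5.1 program, per the labels. Dye and pool were therefore confounded, and the labels do not say whether the 2 arrays came from independent cultures.

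The deposited values were log2 ratios of the 2 dyes, as read from the values themselves: turned back to a linear scale, 99.985% of the values of array 1 and 99.975% of those of array 2 were whole hundredths within 0.001. Such rounding makes ratios far below 1 coarse. The normalization behind them and the dye in the numerator are not given in the sources used here. The deposited columns had a median of -0.136 on each array. The value table holds no intensities, so signal over background is unknown and no loess correction or filter on dim features was possible. Of 22575 features, 20036 had a value on at least 1 array. The platform annotation named 18794 features for 5325 genes, 1 gene per feature and 0 with several, and symbols were updated through the yeast gene table of assembly R64, to which 4 symbols had no match. The other 1242 features with values were unnamed and entered no test of strains. Features fell into 2 blocks with the same order of genes, 1 feature of each gene or more in each block. They were taken for the pair of tags of a strain and are called the first and the second tag, since no source says which block is upstream.

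The sign of every value was turned, so that a value is log2 of the LCD1 pool over the control pool in the likely direction, for the reason given with the LCD1 strain. Features of a gene were averaged within a tag block, each block of each array was centred on its median, and the 2 tags were averaged, so that each array gave 1 value per strain (R 4.3.3). Strain values were tested against 0 with limma 3.58.1 (lmFit with an intercept and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05), with 1 residual and 2.42 prior degrees of freedom. A size rule counted strains at least 2-fold apart in the same direction on both arrays, beside 10000 random pairings of strains between the arrays. A further count asked for the same on both tags of both arrays. Tested on simulated data with 5325 strains, limma called 0% of the strains changed by a log2 of -3, whereas the size rule found 100% of those at -3 or -2, 97.5% of those at 2, 12.5% of those at -1, 27.5% of those at 1 and 0.507% of the unchanged strains. The moderated test thus had no power for single strains in this simulation. Its spreads were drawn from the SDs of 2 arrays, themselves uncertain, so power on the real arrays was not measured.

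Before the data were examined, 22 gene lists were fixed, covering the checkpoint, replication, repair, chromatin, transcription, protein turnover, growth, mating, meiosis and selection functions that LCD1 or the method could touch. They were tested with cameraPR of limma on the moderated statistic with a preset correlation of 0.01, adjusted over the lists. The percentile of each list median among 10000 random lists of its size was also taken. Older gene names were updated where the name belonged to 1 gene. 1 checkpoint entry, CRT1, belonged to several and was left out, as were members with no feature. LCD1 belonged to no list. The named strains also followed a rule made before the data were examined. LCD1 came first. If fewer than 10 strains passed limma's test, the 15 lowest and 10 highest of those past the size rule with the same sign on all tag values were taken, and from each list the 3 members with the largest absolute mean. Values are means ± SD of 2 arrays (n = 2) unless a single tag or array is named. Alternatives covered the centring, the tags used, scale normalization, the threshold, the list test and leaving out either array. The alternatives set as upstream or downstream tags alone were run as first or second tag alone. No chromosome positions are given because the sources state no genome build for the arrays.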

Results

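The arrays compared, strain by strain, a pool of haploid yeast deletion strains that overexpressed LCD1 with a pool that carried a control plasmid. LCD1, also named DDC2, encodes the partner of the checkpoint kinase Mec1, and the plasmid placed it under the galactose-inducible GAL1 promoter. Each strain lacks 1 gene and carries a pair of short DNA tags, so the ratio of tag signals reports the relative abundance of the strain. Per its title, the series asked which deletions are synthetically lethal with LCD1 overexpression. There was 1 comparison, measured on 2 arrays of the same dye orientation, with 20000 features with a value on array 1 and 20032 on array 2. Those values covered 5325 named strains, of which 5309 had both tags on both arrays. The number of arrays limits the precision.

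The LCD1 deletion strain had the highest mean tag ratio of all 5325 strains, a log2 ratio of 2.63 ± 0.0086 (SD, n = 2). The small SD hides tags that lay far apart. Its first tag read 4.24 on array 1 and 4.97 on array 2, and its second tag 1.01 and 0.30, which ranked 455 and 1315 from the top among second tags. This strain (YDR499W) also set the sign of all values. The deposited ratios of its tags were 0.05, 0.03, 0.44 and 0.73, all below 1, and a haploid without the essential LCD1 gene can grow only with the LCD1 plasmid. Its reading in the control pool should then be background, and the ratio gives no fold of abundance. Together with the scanner's usual order of Cy5 over Cy3, this made control over LCD1 pool the likely direction of the deposited ratio, which was turned over here. The rank of LCD1 is therefore not independent evidence of the direction. Were the deposited ratio LCD1 over control pool instead, LCD1 would rank lowest of the 5325 strains, and every strain and list given here as lower would be higher and the reverse. By limma its adjusted p was 0.0941, which did not pass.

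Deletions of replication fork and checkpoint genes were among the strains with the lowest abundance in the LCD1 pool. Strains without TOF1 and CSM3, which encode a complex that moves with the fork, were lower by log2 values of -2.29 ± 0.040 and -1.54 ± 0.33. The 3 strains without the cullin RTT101 and its partners MMS22 and MMS1 stood at -2.16 ± 0.38, -2.87 ± 0.12 and -1.59 ± 0.075, and the strain without the flap endonuclease RAD27 at -1.68 ± 0.19. The tags of the strains without MEC1, the kinase that Lcd1 binds, and SLD3, a replication initiation factor, read -3.38 ± 0.49 and -3.60 ± 0.23. Both genes are essential and their deletion haploids should grow in neither pool, so these readings are tag ratios and no measure of growth. All 8 of these strains were at least 2-fold lower on both tags of both arrays.

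The both-tag rule took 20 strains on the lower side. Besides these 8 they lacked the GPI-anchor synthesis gene MCD4 (-3.01 ± 0.86), SCD5 (-2.88 ± 0.31), the ribosome biogenesis gene RRP12 (-2.83 ± 0.22), the arginine permease gene CAN1 (-1.85 ± 0.38), the nuclear pore gene GLE2 (-1.81 ± 0.42), the mannosyltransferase gene MNN11 (-1.76 ± 0.13), the mRNA 3' end processing gene PCF11 (-1.74 ± 0.15), SET6 (-1.68 ± 0.18), the helicase gene RAD3 (-1.67 ± 0.21), the SAGA gene SGF29 (-1.54 ± 0.21), the P-type ATPase gene SPF1 (-1.29 ± 0.049) and the arginine regulator gene ARG81 (-1.28 ± 0.022). MCD4, SCD5, RRP12, PCF11 and RAD3 encode essential proteins too, and the same limit holds for them. For the other strains, CAN1 among them, signal over background is unknown, so background readings are not excluded. On the higher side it took 8 strains. They lacked the ribosomal protein gene RPL34B (1.99 ± 0.091), the phosphate regulator gene PHO4 (1.71 ± 0.030), the mitotic exit kinase gene DBF2 (1.69 ± 0.098), HAL1 (1.43 ± 0.17), the Paf1 complex gene CDC73 (1.39 ± 0.022), the DNA polymerase epsilon gene DPB3 (1.27 ± 0.028), the vacuolar protease gene PRB1 (1.26 ± 0.24) and the Mediator gene NUT1 (1.25 ± 0.013). When the tag blocks were paired at random, this rule took a mean of 1.52 lower and 1.43 higher strains and at most 8 and 7.

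**Figure D1:**
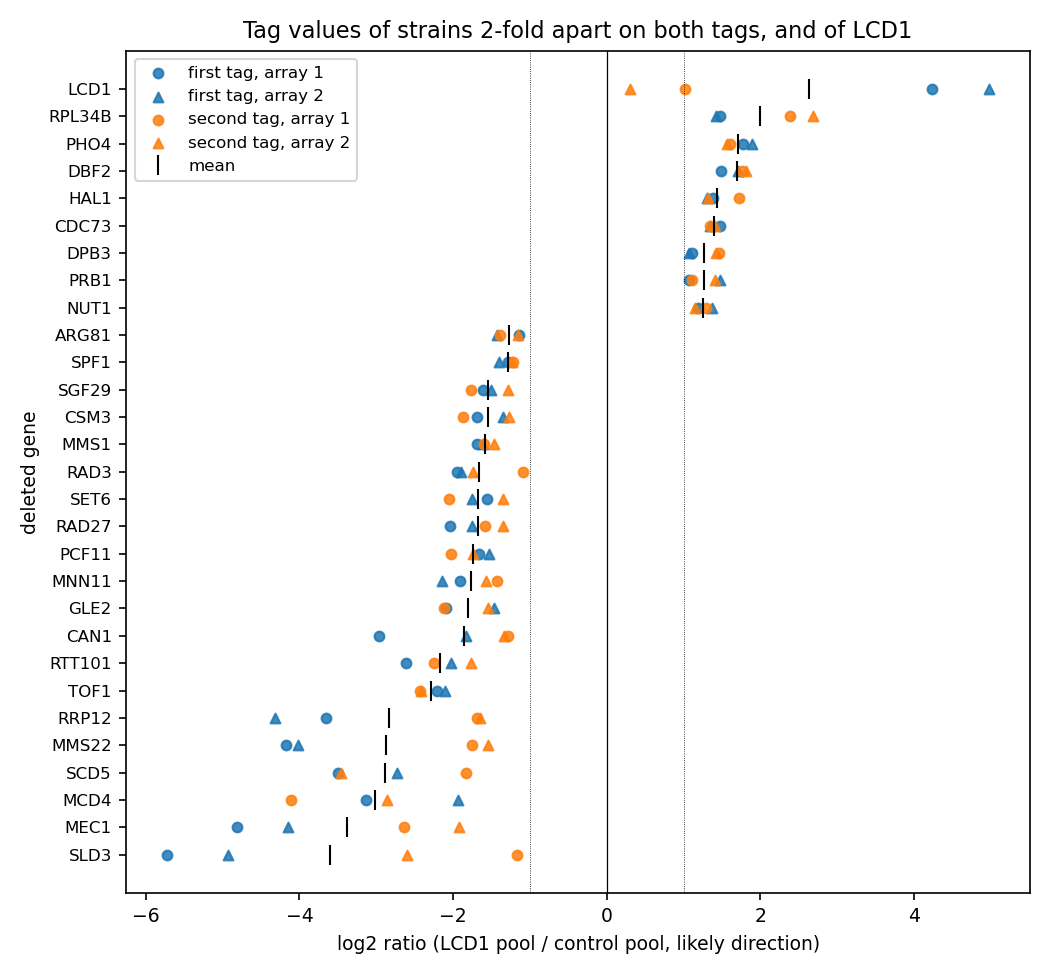
Log2 ratio (LCD1 pool over control pool, likely direction; x axis) of each tag on each array for the strains (y axis) at least 2-fold apart on both tags of both arrays, with LCD1 added. Coloured points are single tag values and black ticks are strain means. The 20 lower strains run from -3.60 (SLD3) to -1.28 (ARG81), the 8 higher from 1.25 (NUT1) to 1.99 (RPL34B), and the tags of LCD1 lie far apart.

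No single strain passed limma's test. It called 0 strains lower and 0 higher (lowest adjusted p 0.0941). At an unadjusted p under 0.05 limma gave 573 lower and 616 higher, 1189 in all, where chance would give 266 in all. A limma fit of the 4 tag values of each strain called 1 strain lower, TOF1 (adjusted p 0.0498), and 0 higher, so that of the gene lists below it called a member of the checkpoint list alone. The 2 tags of an array come from the same pair of pools, so this fit counts more values than there are arrays and its p is too small. By the size rule, 97 strains were at least 2-fold lower and 37 at least 2-fold higher on both arrays, where random pairing gave a mean of 5.23 and 6.53 and at most 16 and 17. The share of lower strains, 72.4%, was 56.5% (78 lower and 60 higher) without centring, 86.2% (56 and 9) after scale normalization and 27.3% (30 and 80) with the second tag alone. With the sign turned, the share of 72.4% would be 27.6%. On array 2 alone 150 strains were 2-fold lower and 137 higher, and on array 1 alone 185 and 253.

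Of the strains past the size rule, 57 lower and 33 higher had the same sign on all tag values. The 15 lowest of these included, besides strains named above, the deletions of the small-subunit processome gene FCF1 (-2.85 ± 0.032), TAO3 (-2.71 ± 1.60), the ribosomal protein gene regulator IFH1 (-2.65 ± 0.16), RPL17B (-2.58 ± 0.47), the leucine regulator LEU3 (-2.49 ± 0.45), the histone gene regulator SPT10 (-2.46 ± 0.13) and the GPI-anchor gene GPI11 (-2.22 ± 0.53). FCF1, TAO3, IFH1 and GPI11 here, and DIP2 among the highest strains, are essential genes, so their values too are no measure of growth. In several of these 1 tag carried most of the value: for FCF1 the first tag read -4.99 and -5.64 and the second -0.67 and -0.11. The 10 highest also included the deletions of the rRNA processing gene DIP2 (2.38 ± 1.40), IZH1 (1.88 ± 1.17), PIB2 (1.53 ± 0.38), the GPI-anchor gene GPI1 (1.51 ± 0.16) and the transcription factor gene HCM1 (1.46 ± 0.18). The values of DIP2 on the 2 arrays, 1.39 and 3.37, and of IZH1, 1.06 and 2.71, differed widely. In each, 1 tag value on array 2 stood out, in the range where rounding of the deposited ratios is coarse. For DIP2 it was the second tag, at 6.49 against 2.08 on array 1, with 0.70 and 0.25 for the first. For IZH1 it was the first tag, at 4.97 against 1.56 on array 1, with 0.56 and 0.45 for the second.

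**Figure D2:**
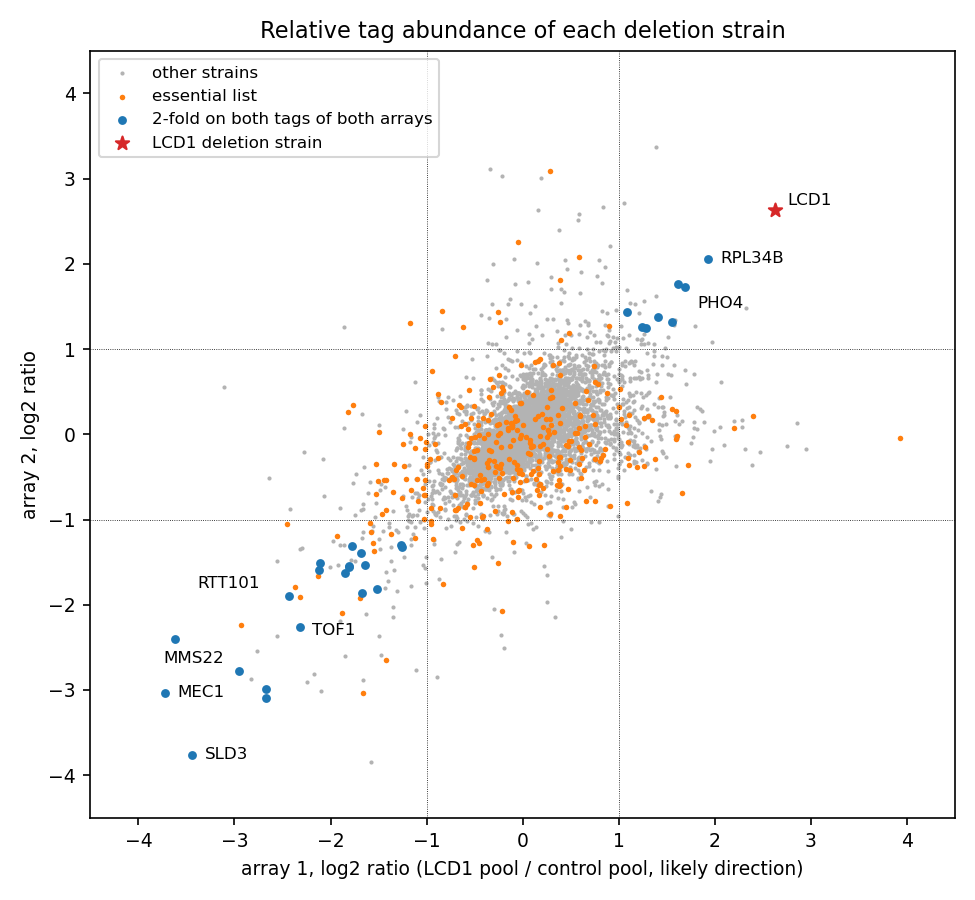
Log2 ratio (LCD1 pool over control pool, likely direction) of each of 5325 strains on array 1 (x axis) and array 2 (y axis), mean of 2 tags. Orange points are the essential list, blue points the strains at least 2-fold apart on both tags of both arrays, the star is LCD1, and dotted lines mark 2-fold. MEC1, SLD3, MMS22 and TOF1 lie at the lower left, and Pearson's r across strains is 0.547.

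Strain values repeated between arrays more than between tags. Across 5325 strains, which are not independent replicates, Pearson's r between arrays was 0.547 and Spearman's rho 0.539. For the first tag alone r was 0.661 and rho 0.578, and for the second 0.296 and 0.439. Between the first and the second tag r was 0.0875 on array 1 and 0.137 on array 2, and rho 0.172 and 0.242.

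The replication fork and S-phase list lay lower in the LCD1 pool. The median of its 23 measured strains was -0.44 (quartiles -0.78 and 0.03), with 16 below 0 and 7 above. By the size rule 5 were lower, the deletions of MMS22, RTT101, RAD27, MMS1 and the fork scaffold gene CTF4 (-1.20 ± 0.051), and 1 was higher, that of DPB3. The adjusted p was 1.1e-05 by cameraPR, and adjusted p = 0.619 with an estimated correlation. The second of these tests had 1 residual degree of freedom, and its lowest unadjusted p for any list was 0.158. It could therefore hardly call any list, here or below. By limma 0 members passed over all strains, 11 passed adjusted over the list alone and 14 had an unadjusted p under 0.05, and the fit of 4 tag values called 0 of them. At the other end, after DPB3, came the deletion of the topoisomerase gene TOP1 (0.83).

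The DNA damage and replication checkpoint list also lay lower, with a median of -0.29 (quartiles -0.61 and 0.08) and 13 of 21 strains below 0. Its 5 members past the size rule were the deletions of MEC1, TOF1, CSM3, the checkpoint clamp gene DDC1 (-1.06 ± 0.057) and XRS2 (-1.05 ± 0.029). The strain without the kinase gene CHK1 stood at 0.55 ± 0.36, and those without the kinase genes RAD53 (0.08 ± 0.42) and TEL1 (0.06 ± 0.17) and the adaptor gene RAD9 (0.17 ± 0.33) had opposite signs on the 2 arrays. RAD53 is essential, so its reading, like that of MEC1, is no measure of growth. The adjusted p was 1.1e-05 by cameraPR, and adjusted p = 0.619 with an estimated correlation. Over all strains 0 members passed in limma, 6 passed adjusted over the list alone and 9 had an unadjusted p under 0.05, while the fit of 4 tag values called 1, TOF1. Without MEC1 the list had a cameraPR adjusted p of 0.000955 (range over 14 alternatives 1.1e-06 to 0.619).

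Strains without homologous recombination genes had a median of -0.24, with 11 of 15 below 0. Of the nuclease complex members, the deletions of RAD50 (-1.07 ± 0.17) and XRS2 (-1.05 ± 0.029) were lower by over 2-fold on average, while that of MRE11 stood at -0.10 ± 0.11. XRS2, the 1 member past the size rule, is in the checkpoint list as well. The cameraPR adjusted p was 0.043, and adjusted p = 0.619 with an estimated correlation. The call held in 6 of 14 alternatives (adjusted p 0.0082 to 0.758) and ended, among others, without the largest member (0.186), by Fisher's exact test of 2-fold members (0.758) or with the first tag alone (0.592). By limma 0 members passed over all strains, 2 adjusted over the list alone and 6 at an unadjusted p under 0.05.

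The uracil and arginine synthesis list had a median of -0.21, with 9 of 13 strains below 0. The deletions of the arginine genes ARG1 (-1.62 ± 0.27) and ARG3 (-1.10 ± 0.13) were past the size rule on the lower side, and that of URA1 stood at -0.80 ± 0.17. The first tag carried most of these values: on arrays 1 and 2 it read -3.65 and -2.68 for ARG1 and -2.09 and -1.49 for URA1, against 0.79 and -0.94 and 0.26 and 0.13 for the second. URA1 is needed to make uracil and the plasmids were selected by URA3, so its haploids should grow in neither pool and its value is no measure of growth. For ARG3 the first tag read -1.67 and -1.94 and the second -0.73 and -0.08. Signal over background is unknown, so the values of ARG1 and ARG3 may be background readings as well. The strain without CPA1, also of arginine synthesis, stood at 0.78 ± 0.12. The cameraPR adjusted p was 0.043, and adjusted p = 0.619 with an estimated correlation. With the second tag alone the test statistic turned upward (adjusted p 0.947) while the median stayed below 0 at -0.022, and the call held in 5 of 14 alternatives (0.0419 to 0.947). In limma, 0 members passed over all strains, 5 adjusted over the list alone and 5 at an unadjusted p under 0.05.

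The 335 strains of the essential list, whose haploids should not grow in either pool, had a median of -0.12, with 203 below 0 and 132 above. SLD3, the proteasome gene PRE6 (-2.59 ± 0.49) and the lipid transfer gene SEC14 (-2.35 ± 0.97) gave the largest values. The cameraPR adjusted p was 2.5e-04, and adjusted p = 0.619 with an estimated correlation. The tags differed in direction: the list medians were -0.42 and -0.61 for the first tag on arrays 1 and 2, and 0.32 and 0.10 for the second, and the test of the second tag alone turned upward (adjusted p 0.0605). Without centring the list median was 0.0075. The list held 17 of the 97 lower strains and 0 of the 37 higher ones by the size rule, and 1 of the 20 lower by both tags, SLD3, although MEC1, MCD4, SCD5, RRP12, PCF11 and RAD3, also among the 20, are essential genes outside the list. The call held in 11 of 13 alternatives (adjusted p 1.6e-12 to 0.619). With the first tag alone it held 76 of 270 lower strains (28.1%, against 6.29% of all strains, Fisher's exact test, two-sided p 1.2e-31). By limma 0 members passed over all strains, 11 adjusted over the list alone and 95 at an unadjusted p under 0.05.

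Strains without subunits of SAGA, Mediator and Swi/Snf, coactivators of RNA polymerase II, lay higher in the LCD1 pool. Their median was 0.34 (quartiles 0.11 and 0.64), with 26 of 32 above 0. The Mediator deletion NUT1 (1.25 ± 0.013) and the SAGA deletion ADA2 (1.13 ± 0.45) were the highest, while SGF29 (-1.54 ± 0.21), also of SAGA, and GAL11 (-0.90), of Mediator, went the other way. The cameraPR adjusted p was 0.0203, and adjusted p = 0.619 with an estimated correlation. The call held in 11 of 14 alternatives (0.0022 to 1) and also ended with the first tag alone (0.488) and by Fisher's exact test of 2-fold members (adjusted p 1). With the second tag alone the cameraPR adjusted p was 0.0030. List medians were 0.17 and 0.19 for the first tag on arrays 1 and 2, and 0.32 and 0.53 for the second. The essential list stood at -0.42 and -0.61 for the first tag and at 0.32 and 0.10 for the second. The second tag thus does not set these lists apart on array 1, and whether background readings contribute was not tested. In limma, 0 members passed over all strains, 8 adjusted over the list alone and 14 at an unadjusted p under 0.05.

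3 further lists lay higher by small amounts. Strains without cytosolic ribosomal proteins had a median of 0.16, with 49 of 72 above 0, led by RPL34B, RPL12B (1.39 ± 1.42) and RPL24B (1.02 ± 0.088). Strains without respiratory chain or mitochondrial translation genes also had a median of 0.16, with 48 of 62 above 0, led by MRPS12 (1.06 ± 0.23), QCR10 (0.86 ± 0.055) and MRPL7 (0.72 ± 0.33). Strains without pheromone response genes had a median of 0.22, with 17 of 25 above 0, led by the kinase STE20 (1.33 ± 0.30), the transcription factor STE12 (1.19 ± 0.54) and the adaptor STE50 (0.998 ± 0.43). The cameraPR adjusted p values were 0.0404, 0.0404 and 0.043, and each list had adjusted p = 0.619 with an estimated correlation. These calls held in 10, 8 and 8 of 14 alternatives, and all 3 ended without the largest member. By limma 0 members of each passed over all strains, 1, 0 and 3 adjusted over the list alone, and 16, 11 and 7 at an unadjusted p under 0.05.

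**Figure D3:**
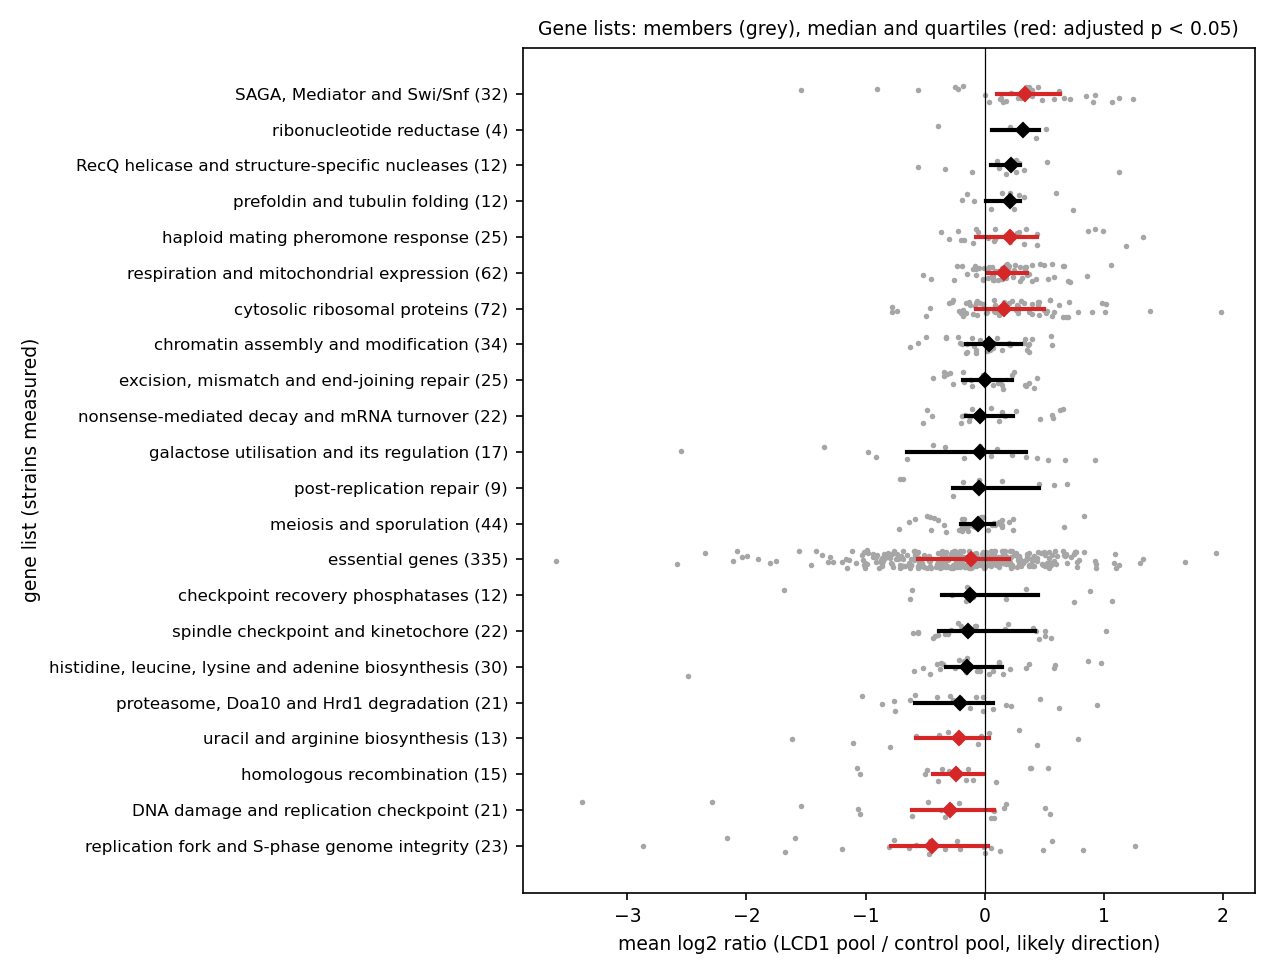
Mean log2 ratio (LCD1 pool over control pool, likely direction; x axis) of the members of each gene list (y axis, number of strains measured in brackets). Grey points are strains, diamonds are list medians, bars span the quartiles, and red marks lists with a cameraPR adjusted p under 0.05 at the preset correlation. The replication fork list has the lowest median (-0.44) and the SAGA, Mediator and Swi/Snf list the highest (0.34).

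The other 13 lists did not pass, though 4 of them passed in some of 14 alternatives. These were the galactose list in 2 (adjusted p 0.0616, lowest 0.0011 with the first tag alone), the proteasome list in 1 (0.0733, then 0.0495 without essential strains), and, with the second tag alone, the meiosis list (0.233, then 0.0124) and the ribonucleotide reductase list (0.563, then 0.0272). Medians were -0.21 for proteasome and protein degradation genes, -0.15 for histidine, leucine, lysine and adenine synthesis, -0.14 for the spindle checkpoint and kinetochore, -0.12 for checkpoint recovery phosphatases, -0.06 for meiosis and sporulation, -0.05 for post-replication repair, -0.04 for galactose utilisation and -0.04 for nonsense-mediated decay and mRNA turnover. They were 0.0034 for excision, mismatch and end-joining repair, 0.03 for chromatin assembly, 0.22 for prefoldin and tubulin folding, 0.22 for RecQ helicase and nuclease genes and 0.33 for ribonucleotide reductase. The test statistic of the chromatin and excision repair lists pointed downward and that of the decay list upward, against their medians. In the galactose list, the deletions of GAL10 (-2.55 ± 0.65) and GAL7 (-1.35 ± 0.030), enzymes of galactose breakdown, were past the size rule. The first tag of GAL10 read -4.88 and -5.35, and its second tag 0.69 and -0.67. With galactose as the only carbon source these haploids should grow in neither pool, so both are tag ratios and no measure of growth. Other large single values in these lists were those of the phosphatase gene PSY4 (-1.69 ± 0.47), the proteasome regulator RPN4 (-1.03 ± 0.27), RMI1 (1.13 ± 0.75) and BIM1 (1.02 ± 1.23).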

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

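The 2 tests of the replication fork list, and the interval of the count by both tags, were chosen after the results had been seen, and the other tests here before their results. Values also repeated between arrays in features to which the platform annotation gives no gene. Of 617 such feature pairs with values in both tag blocks on both arrays, 20 were at least 2-fold apart in the same direction on both arrays, 11 lower and 9 higher. Random pairing between the arrays gave a mean of 1.44 and at most 7. Of the named strains, 134 of 5325 were past the same rule. Both arrays had the same dye orientation, so a fixed dye bias of these features would repeat as well. Whether they tag strains, and which, could not be told from the annotation.

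Values of a strain repeated between arrays within a tag block (r 0.661 for the first) but little between its tags (r 0.0875 and 0.137, rho 0.172 and 0.242). If tags of haploids that cannot grow read near background, strains of the essential list should lose their first-tag difference on the second tag more often than strains of other lists. Of the essential strains 2-fold apart by the first tag, 11.7% (9 of 77) had a second tag of the same sign on both arrays with a mean log2 of at least 0.5 in size, against 40.5% (17 of 42) in the other lists (Fisher's exact test, two-sided p 0.000459). This is consistent with background readings as part of the low agreement. No biological explanation was tested, and tags that failed in single strains stay open.

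There were more strains 2-fold lower than 2-fold higher (97 and 37). If the excess came from the dye ratio of background features in the first tag block, it should be absent from the second. With the first tag alone 73.4% of the 2-fold strains were lower, and with the second 27.3% (exact 95% interval 19.2 to 36.6), so part of the excess may come from the first tag block. Among strains 2-fold apart on both tags of both arrays, 71.4% were lower (20 and 8, exact 95% interval 51.3 to 86.8). Random pairing of the tag blocks, which keeps the lean of each block, gave means of 1.52 lower and 1.43 higher. If the tags were unrelated, the leans of both blocks together would thus give a nearly even split here. The second block leaned the other way (30 lower and 80 higher). Random pairing therefore does not show what the lean of the first block alone would give. The interval reaches near an even split, and several of those 20 are essential genes, so the source of this excess stays open. Dye and pool were also confounded, so whether LCD1 overexpression harmed more strains than it helped cannot be read from these counts.

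The replication fork list lay lower. The dye ratio of background features would put it on the side of the essential list, above 0, for the second tag. It stood at -0.56 there on array 1, below all 10000 random lists of its size, and at -0.38 on array 2 (percentile 0.02), which argues against this explanation. A loss of slow-growing strains in general would lower the ribosomal protein, respiration and coactivator lists too, and the lowest of their 3 medians was 0.16. These medians were known when the test was chosen. With the second tag alone on arrays 1 and 2 they were -0.020 and 0.020 (ribosomal), 0.028 and 0.30 (respiration) and 0.32 and 0.53 (coactivators). The test therefore does not exclude slow growth as a cause. Dye bias of single tags, confounded with the pool, slow growth and an effect of LCD1 overexpression on these strains all stay open. A dye-swapped array or growth of the single strains would test these. The call was lost with an estimated correlation (adjusted p 0.619), in a test that could hardly call any list.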

How the results depend on the processing

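The fit of 4 tag values, Fisher's exact test of 2-fold members, and lists without their largest member were chosen after seeing the data. The fork and checkpoint lists stayed lower with adjusted p under 0.05 in 13 of 14 alternatives. They lost the call only in the test with an estimated correlation, which could hardly call any list. LCD1 ranked first under every centring, second after scale normalization and 637 with the second tag alone. The cause of the changes below was not tested unless stated. Leaving values as deposited moved the median of all strains by 0.13. It gave 60 higher strains by the size rule, 3 lists lower and LCD1 2.75. Of 22 list medians, 6 turned sign without centring, 6 with the first and 6 with the second tag alone. The first tag alone gave 270 lower and 98 higher strains, 2 lists higher, SAGA, Mediator and Swi/Snf at adjusted p 0.488, and LCD1 4.60. The second tag alone gave 30 lower and 80 higher, 2 lists higher, LCD1 0.66 and turned directions for the essential list (adjusted p 0.0605), the uracil and arginine list (0.947) and GAL10 (0.011). Scale normalization gave 56 lower and 9 higher, 3 lists lower and LCD1 2.93. At adjusted p under 0.1, limma called 7 strains lower and 1 higher, LCD1. The size rule gave 231 lower and 206 higher at 1.5-fold, 28 and 4 at 3-fold, and 20 and 8 on both tags, by construction. With an estimated correlation 0 lists were lower and 0 higher (cameraPR at the preset correlation called 5 and 4), and the fork, checkpoint, essential and SAGA, Mediator and Swi/Snf lists had adjusted p 0.619. The lowest unadjusted p of any list was then 0.158, from a test with 1 residual degree of freedom. Its loss of all calls therefore does not show that correlation between members removed them. Estimated correlations were -0.028 (fork), -0.029 (checkpoint), 0.0090 (essential) and 0.0040 (SAGA, Mediator and Swi/Snf). CameraPR on ranks gave 3 lists lower, and on the mean log2 ratio 3 lower and 2 higher. Without array 1 or 2 the size rule gave 150 to 185 lower and 137 to 253 higher, since it then asked for 1 array. The fit of 4 tag values called 1 strain lower, TOF1. Fisher's exact test gave 3 lists lower and 0 higher, with SAGA, Mediator and Swi/Snf at adjusted p 1. Without the largest member 3 lists were lower and 1 higher. Robust eBayes, centring without essential strains and centring both tag blocks together changed no strain or list count by over 1.5 times. Over all lists and alternatives, 262 list calls kept their side, 38 lost and 5 gained the threshold, and 2 turned. With a single array no list was tested. The ordinary one-sample test was used for values alone and gives the same means. No paired analysis was possible because each array holds both pools and there is 1 group of ratios. Signal over background is unknown, so strains near background could not be set aside.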

Other observations

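The groups in this part, their percentiles and the test of the coactivator list were chosen after the values had been seen, so the percentiles describe these arrays and are no independent test. Strains without subunits of mannan polymerase II, which extends the mannose backbone of cell wall glycoproteins in the Golgi, were lower in the LCD1 pool. MNN11 stood at -1.76 ± 0.13, HOC1 at -1.02 ± 0.0091, ANP1 at -0.90 ± 0.26, MNN10 at -0.84 ± 0.16 and MNN9 at -0.28 ± 0.17 (SD, n = 2). All 5 were below 0, and their median of -0.90 lay at percentile 0.01 of random groups of 5. None of these 5 passed limma's test, and all of them but MNN9 had an unadjusted p under 0.05. The 3 other groups below had percentiles of 99.59 (phosphate response), 90.55 (Paf1 complex) and 0 (ligase with ASF1 and RTT109).

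Strains of the phosphate response went in both directions. Those without the activators PHO4 (1.71 ± 0.030), PHO2 (0.64 ± 0.12) and PHO81 (0.63 ± 0.45), which turn on phosphate starvation genes, were higher, as was PHO85 (0.57 ± 0.27), and that without the repressing cyclin PHO80 was lower (-0.66 ± 0.044). PHO80, PHO4, PHO2 and PHO81 kept their sign on both tags of both arrays, at -0.62, -0.58, -0.77 and -0.68 for PHO80. PHO85 read -0.10 on the first tag of array 1 and was above 0 on its other tag values. By its mean PHO85, the kinase partner of PHO80, stood on the other side of 0 from it. Of the Paf1 complex, CDC73 stood at 1.39 ± 0.022, LEO1 at 0.49 ± 0.014, PAF1 at 0.12 ± 0.023 and RTF1 at 0.13 ± 0.033.

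The ligase subunits RTT101, MMS1 and MMS22 act with the histone chaperone ASF1 and the H3 acetyltransferase RTT109. The deletions of ASF1 (-0.76 ± 0.25) and RTT109 (-0.80 ± 0.27) were low by the second tag alone: ASF1 read 0.48 and -0.03 on the first tag and -1.65 and -1.85 on the second, and RTT109 0.37 and -0.49 against -1.59 and -1.49. Arginine genes stood on both sides of 0, with CAN1 at -1.85 ± 0.38, ARG81 at -1.28 ± 0.022, ARG1 at -1.62 ± 0.27 and CPA1 at 0.78 ± 0.12. Whether background readings contribute to these values was not tested. Of the checkpoint clamp, DDC1 stood at -1.06 ± 0.057, MEC3 at -0.47 ± 0.21 and RAD17 at 0.07 ± 0.041.

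The coactivator list lay higher by cameraPR, but lost the call with the first tag alone (adjusted p 0.488) and with an estimated correlation (0.619). A candidate explanation is weaker induction of the GAL1 promoter, and so of LCD1, in strains without these subunits. The SAGA and Mediator members alone, 27 strains, had a median of 0.34, at percentile 99.87 of random lists. They are most of the 32 strains whose high median prompted the explanation. This part of the test could therefore hardly have come out otherwise and lends the explanation no support. Weaker induction as the cause would also put the strain without the GAL80 repressor below 0, if loss of GAL80 raised GAL1 induction on galactose. Whether it did was not measured. That strain stood at 0.53 ± 0.72, with 1.04 on array 1 and 0.02 on array 2. The spread of that single strain leaves the explanation open, and LCD1 expression was not measured.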
